A study of Mus musculus with 6 samples.

How the data were processed

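RNA was measured by sequencing in 6 libraries from E14 cells, a mouse embryonic stem cell line, with 3 libraries labelled control and 3 labelled Rif1-KO. Per the labels' protocols, cells grew on plates coated with 0.1% gelatin in 2i medium, a medium with 2 kinase inhibitors that holds the cells in naive pluripotency, at 37 °C and 5% CO2. The same protocol text, for all 6 libraries, gives 0.1 µM 4-hydroxytamoxifen (4-OHT) for 2 days and then 1 day without it. Libraries were made from 200 ng of total RNA with an mRNA kit, per the labels' protocols. The column names in the file headers carry the letters TAM in the 3 libraries labelled Rif1-KO and 2i in the 3 control libraries, so whether the control cells also received 4-OHT, and whether both groups grew in the same medium, is not settled by the sources used here. How Rif1 was disrupted and which part of it was deleted are not given in the sources used here.

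The authors deposited raw read counts per gene symbol, 1 table per library, with 33924 symbols and no normalization. Reads were aligned with STAR and counted with featureCounts 1.6.2 on the mouse build mm9, per the submitters' processing notes. The annotation version, the strand setting and the handling of reads that map to several places are not given in the sources used here. Without these, counts of near-identical gene copies, of overlapping genes and of antisense partners are uncertain. No coordinates are printed, because the reference used here (GRCm38, with GENCODE and RefSeq annotation) is another build than the one in the notes. That reference served only for current gene names, for the chromosome and order of genes, for transcript GC content and length, and for sequence shared between transcripts. Of the symbols, 28057 matched a gene with a chromosome, and 13763 of the tested genes lay on 1 of 20 chromosomes (the autosomes and X). GC content and length were found for 13894 tested genes (97.5%).

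Total counts per library ran from 8383632 to 10980777. CPM values were computed here from the deposited counts, each divided by its library size after TMM scaling. A gene with 0 counts over the 3 control libraries was given a floor of 3 counts over that group, which is 0.113 CPM, and its fold is then stated as at least that large. Such a fold takes the counts in the libraries labelled Rif1-KO as read, so it is not an exact limit. For the sum over 5 Tdpoz genes it was 25.3, against an exact lower 95% limit of 20.1. For genes with 1 to 3 control counts the ratio is given with an exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

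Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test with group as the only term, all 6 libraries). A gene is said to rise or fall at a Benjamini-Hochberg adjusted p under 0.05 over 14250 tested genes, with no fold minimum. Every adjusted p of a gene comes from this test unless another tool is named. Errors of log2 fold changes are standard errors from the same test, and errors of CPM are SD over 3 libraries. Fold changes are the libraries labelled Rif1-KO over control.

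Before the data were examined, 25 gene lists were fixed, covering cell states, other cell types that a stem cell culture could hold, and functions known for RIF1. They name two-cell-like, naive pluripotency, general pluripotency, formative and primed, germline, primitive endoderm, trophectoderm, mesoderm and primitive streak, neuroectoderm, fibroblast, imprinted, Hox, clustered protocadherin, DNA replication, double-strand break repair and RIF1 partner, heterochromatin and silencing, replication-dependent histone, cytosolic ribosomal protein, p53 target, interferon-stimulated, ERK target, Wnt target, hypoxia and glycolysis, unfolded protein and amino acid response, and cholesterol synthesis genes. They hold 501 distinct symbols, of which 476 were in the table and 388 were tested. The other 25, looked up by the listed symbol alone, are not analysed here. Lists with at least 3 tested members, 24 of the 25, were compared with the remaining genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Benjamini-Hochberg adjustment ran over the 24 lists. The fry test asks instead whether members moved, on balance, one way, without comparing them with other genes.

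The rule for named genes was fixed at the same time. It takes Rif1, then the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries. From each list it takes up to 4 members that passed, in order of adjusted p, or, where none passed, the 2 with the highest expression. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen. For the share of sequence held in common, the longest transcript of each named gene and of each two-cell-like list member was searched for 50-base stretches that also occur in transcripts of another gene. Single values per library were compared by exact two-sided permutation of 3 against 3 libraries, whose smallest possible p is 0.1. Neighbouring genes were compared with 10000 shuffles of gene order within chromosomes.

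The procedure was tested on simulated counts with the real means, library sizes and dispersions, over 14071 genes tested, for Rif1-KO against control. Of 50 genes changed 1.2-fold it recovered 34%, of 50 changed 1.5-fold 78%, of 50 changed 2-fold 92% and of 50 changed 4-fold 100%. False calls made up 6.17% of all calls. Only these genes were changed, a far smaller share than was called in the real data. The shares recovered and of false calls therefore need not hold there. Alternatives covered other scalings, filters on low counts, DESeq2 1.42.0, limma-voom, a robust dispersion, a replicate block, stricter thresholds, other set tests and leaving out each library in turn. An offset for GC content and transcript length (fitted with mgcv 1.9.3), thinning of all libraries to the smallest total, a 2-fold minimum and camera with an estimated correlation and no filter on low counts were added after seeing the data.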

Results

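RNA was sequenced from E14 mouse embryonic stem cells, with 3 libraries labelled control and 3 labelled Rif1-KO. The labels give 2i medium and 4-OHT for all 6, but the file headers carry 2i in the control libraries alone and TAM in the libraries labelled Rif1-KO alone. A difference in medium or drug between the groups is therefore not excluded. The series asks what loss of Rif1, a chromatin protein known for its part in replication timing, break repair and silencing, does to gene expression. Control libraries held 9218036, 8383632 and 9111979 counts, and the libraries labelled Rif1-KO held 10980777, 9833394 and 9185062. The correlation of log CPM across genes ran from 0.993 to 0.995 between libraries of a group and from 0.968 to 0.969 between groups. The first principal component, with 76.9% of the variance, separated the groups. Every pair of libraries within a group differed by more than sampling noise, with chi-square values per degree of freedom from 1.29 to 4.55.

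The targeted gene was still read at nearly the control level. Rif1 stood at 673, 657 and 700.1 CPM in the control libraries and at 602, 604 and 664 CPM in the libraries labelled Rif1-KO. The means were 677 ± 21.9 and 623 ± 35.5 CPM (SD, n = 3), a log2 fold change of −0.12 ± 0.05 with an adjusted p of 0.0509 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This lies next to the threshold, and the call turned on the processing. Rif1 passed under 11 of 18 alternatives, among them DESeq2 (adjusted p = 0.0361), limma-voom (adjusted p = 0.0264), a replicate block (−0.12, adjusted p = 0.0227), the fits without control replicate 2 (−0.14, adjusted p = 0.0343) and without Rif1-KO replicate 3 (−0.17, adjusted p = 0.00486), and an offset for GC content and length (−0.35, adjusted p = 6e-07). It did not pass under the other 7, and over all 18 the adjusted p ran from 6e-07 to 0.212. The offset also lowered the median log2 fold change of all tested genes, from 0.00347 to −0.0696. A count over the whole gene cannot show whether some exons were lost, so it checks neither the presence nor the absence of the deletion, and the groups are therefore named by their labels.

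Expression differed between the groups at 7251 genes (50.9% of those tested), and the large changes were mainly increases. Of 14250 genes tested, 3722 rose and 3529 fell in the libraries labelled Rif1-KO, and 6999 did not pass. Changes of at least 2-fold were called for 748 genes that rose and 186 that fell. Of the 748, 252 (33.7%) had a control mean under 1 CPM, among them Zscan4c, while Dnmt3l was among the remainder. Of the 186 that fell, 51 had a mean under 1 CPM in the libraries labelled Rif1-KO. The groups' libraries did not overlap at 8151 genes (57.2% of those tested), where chance gives 10%. With the offset for GC content and length, added after seeing the data, the division shifted to 2966 higher and 4580 lower. The offset also moved the median log2 fold change of all tested genes from 0.00347 to −0.0696. The 2 divisions are therefore not centred alike, and the shift toward lower calls is not one of GC content and length alone.

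**Figure D1:**
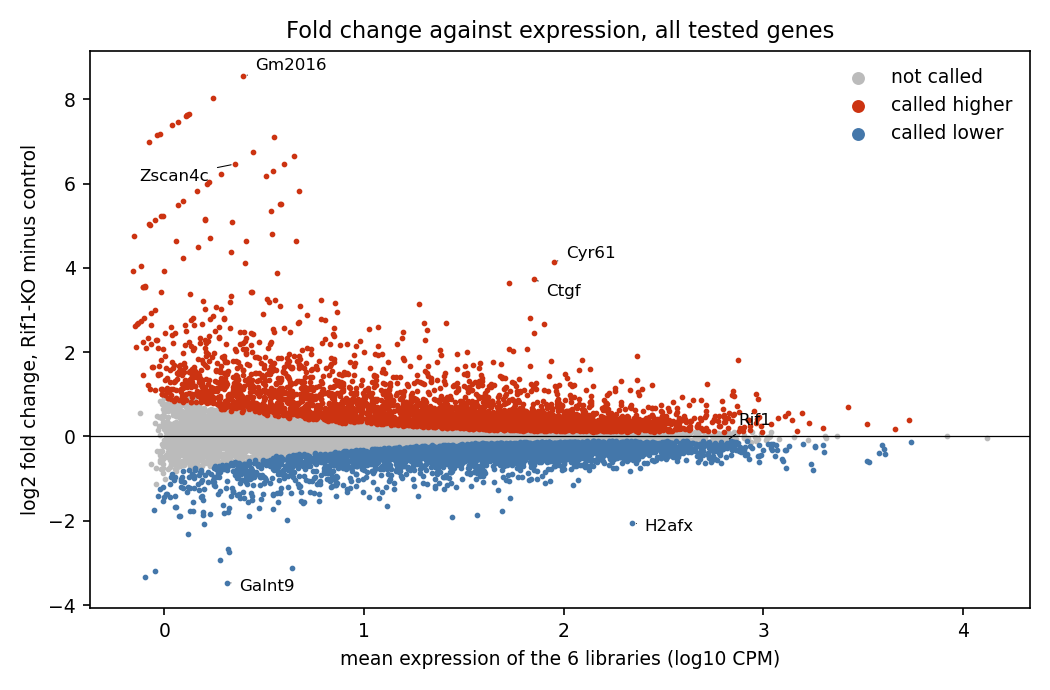
Log2 fold change (Rif1-KO minus control, vertical axis) against mean expression over the 6 libraries (log10 CPM, horizontal axis) for the 14250 tested genes, 1 point per gene. Red points rose (3722 genes), blue points fell (3529 genes) and grey points did not pass; Gm2016 and Zscan4c lie at the top left, H2afx and Galnt9 below, and Rif1 near 0.

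Genes of the two-cell-like state, a rare state of embryonic stem cells that transcribes genes of the two-cell embryo, rose from near silence. The 29 members of that list in the table summed to 1.62 ± 0.324 CPM in control and 76.1 ± 2.95 CPM in the libraries labelled Rif1-KO (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), a ratio of counts of 46.9 (95% interval 34.7 to 65.0). Of the 29, 23 had more counts per library total in the libraries labelled Rif1-KO, none had fewer and 6 had no count in any library. All 15 tested members rose, but the filter on low counts fixed that direction. Their control means were at most 0.304 CPM, under the filter's limit of 1.09 CPM, so each was tested only because it was read in the libraries labelled Rif1-KO. The 14 members left out by the filter summed to 0.292 ± 0.253 CPM in control and 5.79 ± 0.767 CPM in the libraries labelled Rif1-KO (exact p = 0.1). Gm5662 went from 0.146 ± 0.126 to 9.30 ± 0.255 CPM (SD, n = 3; log2 fold change 5.83 ± 0.33, adjusted p = 2.14e-11). Dub1, a deubiquitinating enzyme gene, rose from 2 to 236 counts per group, a ratio of 104 (95% interval 28.5 to 863), and Dub1a from 2 to 209, a ratio of 92.0 (25.2 to 765). Summed over 6 entries of the Zscan4 family of zinc finger genes, the pseudogene Zscan4-ps2 among them, expression was 0.301 ± 0.228 CPM in control and 19.7 ± 0.582 CPM in the libraries labelled Rif1-KO, a ratio of 65.3 (32.9 to 152). The sum over 5 Usp17 and Dub genes rose from 0.493 ± 0.236 to 33.6 ± 1.86 CPM, a ratio of 68.5 (39.9 to 129). These sums over families, the sums over members and Zscan4c were chosen after their values were seen.

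The median log2 fold change of the tested members, raised by the same filter, was 6.17, or 5.52 with members lacking control counts set at their bound. Camera's adjusted p on the tested members, 8.66e-11 and, with an estimated correlation, 0.0217, rests on that selection as well. With every gene read at least once kept, whichever group it was read in, 23 members entered and camera's adjusted p was 5.67e-16. With an estimated correlation it was 0.0181, a setting added after seeing the data. Members without a control count, such as Spz1, entered there only for their counts in the libraries labelled Rif1-KO. The selection is therefore not fully removed. Many members share sequence with near-identical copies, so the count of a single copy is uncertain: 7 of the 15 shared over 50% of their 50-base stretches with another gene, such as Zscan4c with 85.5%. Spz1 (0%) and Zfp352 (7.10%), the latter chosen after its values were seen, shared little or none.

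Of the 12 largest increases, Tdpoz3 and Spz1 are on the two-cell-like list. Tmem92-ps is there too under its current name, Tmem92, but was not counted with the list, which was matched by symbol. Gm2016 had no control count and 4.96 ± 0.260 CPM (SD, n = 3) in the libraries labelled Rif1-KO, at least 43.8-fold higher. Gm6189 was at least 30.2-fold higher, Gm11784 and Trim75 each at least 23.2-fold, Tdpoz3 at least 22.9-fold, Gm12800 at least 22.6-fold and Spz1 at least 20.6-fold. Zscan4-ps2 was at least 19.4-fold higher, Gm11292 at least 16.7-fold, Abcb5, a membrane transporter gene, at least 16.4-fold and Gm13109 at least 14.7-fold. Tmem92-ps had 1 control count and 212 in the libraries labelled Rif1-KO, a ratio of 187 (95% interval 33.2 to 7410). By edgeR's quasi-likelihood test the adjusted p ran from 7.94e-11 for Tmem92-ps to 6.17e-06 for Gm13109. The rule for named genes required all 12 to pass. The filter on low counts kept them only for their counts in the libraries labelled Rif1-KO. Their p-values are therefore no separate support for the rise. Gm6189 (100% shared), Gm2016 (81.3%), Zscan4-ps2 (87.6%) and Tdpoz3 (66.2%) share most of their sequence with other genes, whereas Trim75, Spz1, Gm11292 and Abcb5 share none.

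Among the 12 largest decreases, H2afx had the highest expression. This gene, which encodes the histone variant H2AX that is phosphorylated at DNA breaks, fell from 357 ± 10.4 to 85.6 ± 2.44 CPM (SD, n = 3; log2 fold change −2.06 ± 0.05, adjusted p = 2.68e-17). Cplx1, a regulator of synaptic vesicle release, fell from 7.87 ± 1.29 to 0.887 ± 0.200 CPM, and Cdh22, a cadherin, from 6.57 ± 0.849 to 1.69 ± 0.667 CPM. A further 8 had under 4 CPM in control. Galnt9 was 11.1-fold lower and 1700060C20Rik 10.2-fold lower, with log2 fold changes of −3.47 ± 0.41 and −3.34 ± 0.49. Cox6a2, a muscle subunit of cytochrome oxidase, had −2.94 ± 0.31, the glutamate receptor gene Grm2 −2.74 ± 0.33, the uncoupling protein gene Ucp1 −2.67 ± 0.36, Lrrn2 −2.31 ± 0.35 and the histamine receptor gene Hrh3 −2.07 ± 0.35. Hist2h3c1 fell by 3.19 ± 0.54 on the log2 scale, but shares 100% of its sequence with other genes.

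**Figure D2:**
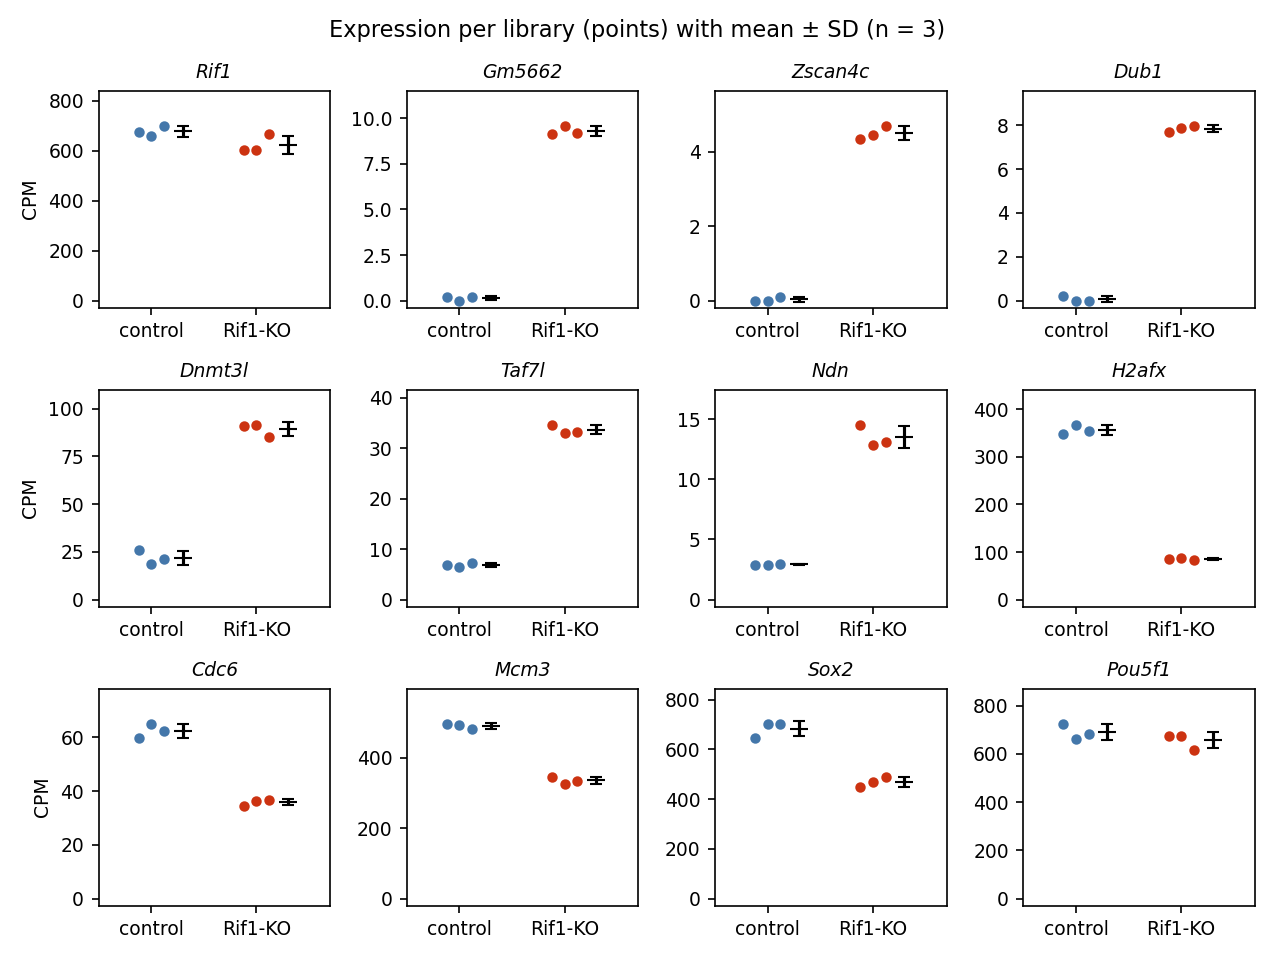
Expression (CPM, vertical axis from 0) of 12 genes in each library, with blue points for the 3 control libraries and red points for the 3 libraries labelled Rif1-KO, and black bars for mean ± SD. Rif1 and Pou5f1 overlap between groups, Gm5662, Zscan4c, Dub1, Dnmt3l, Taf7l and Ndn are higher and H2afx, Cdc6, Mcm3 and Sox2 lower in every library labelled Rif1-KO.

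Pluripotency genes moved in both directions, and camera set none of their 3 lists apart from the remaining genes. Among 19 tested naive pluripotency genes, 6 rose, 6 fell and 7 did not pass. Fbxo15 rose from 259 ± 4.20 to 411 ± 0.256 CPM (SD, n = 3; log2 fold change 0.66 ± 0.04) and Tbx3 rose by 0.49 ± 0.05, while Prdm14 fell by 0.88 ± 0.08 and Nr5a2 by 0.47 ± 0.06. Among 16 general pluripotency genes 4 rose, 8 fell and 4 did not pass. Sox2 fell from 683 ± 31.8 to 469 ± 19.4 CPM (log2 fold change −0.54 ± 0.05, adjusted p = 1.78e-08), Sall4 by 0.57 ± 0.04, Lin28a by 0.47 ± 0.04 and Utf1 by 0.67 ± 0.07. Pou5f1, named after its values were seen, stood at 690 ± 32.8 and 656 ± 33.1 CPM and did not pass (adjusted p = 0.232).

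Of 18 formative and primed genes, those of the step after naive pluripotency, 7 rose, 9 fell and 2 did not pass. Dnmt3l, a partner of the enzymes that methylate DNA de novo, rose from 21.9 ± 3.74 to 89.3 ± 3.66 CPM (log2 fold change 2.02 ± 0.08, adjusted p = 1.93e-13). Grhl2 rose from 14.4 ± 1.71 to 43.9 ± 1.53 CPM and Cdh2 by 1.68 ± 0.22, and Otx2 fell by 0.88 ± 0.07. Camera gave adjusted p values of 0.871 for the naive, 0.11 for the general and 0.874 for the formative list. Fry, which does not compare a list with other genes, passed all 3, with adjusted p values of 0.0491 for the naive, 0.000297 for the general and 0.0174 for the formative list. Its direction was down for the general list and up, against camera, for the naive and formative lists. By camera the general list passed without a filter on low counts (adjusted p = 0.0481) and with limma-voom (adjusted p = 0.0448). The formative list had a median log2 fold change of −0.10 but a mean of 0.21, with camera's direction down.

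Camera called none of the 5 lists of markers of other cell types outside the germline, although single markers changed strongly. Of 9 trophectoderm genes, 5 rose, 3 fell and 1 did not pass. The keratin genes Krt8 and Krt18 rose from 22.5 ± 2.20 to 74.2 ± 7.66 CPM and from 25.8 ± 1.36 to 69.9 ± 0.481 CPM (SD, n = 3), and Lgals3, which encodes galectin-3, from 5.04 ± 1.48 to 25.8 ± 1.35 CPM. Tead4 rose by 0.41 ± 0.05 on the log2 scale. The trophectoderm list had an adjusted p of 0.11 by camera and of 5.55e-05 by fry, with direction up. By camera it passed without control replicate 1 (adjusted p = 0.044), without a filter on low counts (adjusted p = 0.0331) and with the offset for GC content and length (adjusted p = 0.0272).

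Of 16 primitive endoderm genes, 7 rose, 4 fell and 5 did not pass. Sparc rose by 0.94 ± 0.05, Dab2 by 1.76 ± 0.15 and Sox17 by 1.61 ± 0.38 on the log2 scale, and Fgfr2 fell by 1.42 ± 0.28. The list's median of 0.05 turned to −0.01 under another scaling (camera adjusted p = 0.576, and adjusted p = 0.00116 by fry, with direction up). Of 8 neuroectoderm genes, 3 rose (Nes, Sox11 and Zic1), 2 fell and 3 did not pass, or 3 each way adjusted over the list alone. Nes went from 46.2 ± 5.66 to 99.8 ± 3.47 CPM and Ncam1 from 85.4 ± 4.97 to 46.6 ± 1.46 CPM. That list had a median of −0.003, a mean of 0.25 and camera's direction up (adjusted p = 0.874), and its median changed sign under another scaling.

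Of 8 mesoderm and primitive streak genes, 3 rose, Gsc fell and 4 did not pass (camera adjusted p = 0.757). Snai1 rose by 1.52 ± 0.31 and Gsc fell by 1.12 ± 0.17 on the log2 scale. Mesp2 (log2 fold change 0.78) and Kdr (0.77) were weaker. With DESeq2 their adjusted p values were 0.124 and 0.155. Mesp2 did not pass without control replicate 1 (0.0592), control replicate 3 (0.0896) or Rif1-KO replicate 1 (0.0999), nor Kdr without control replicate 2 (0.0619), Rif1-KO replicate 1 (0.0581) or Rif1-KO replicate 3 (0.0718). Of 11 fibroblast genes, 2 rose, 2 fell and 7 did not pass (camera adjusted p = 0.879). Thy1 fell by 0.99 ± 0.16 and Vim by 0.24 ± 0.04, and Fn1 rose by 0.18 ± 0.05. Twist1 rose by 0.71 ± 0.22, a call lost with DESeq2 (adjusted p = 0.0887) and without control replicate 1 (adjusted p = 0.0601). Col1a1, a main collagen of fibroblasts chosen after its values were seen, stood at 2.38 ± 1.09 and 2.06 ± 0.744 CPM.

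Germline genes rose on balance, with clear exceptions. Of 30 tested, 22 rose, 6 fell and 2 did not pass, or 23 and 6 adjusted over the list alone. Taf7l, a germ cell relative of a general transcription factor, rose from 6.85 ± 0.380 to 33.7 ± 0.910 CPM (SD, n = 3; log2 fold change 2.29 ± 0.10, adjusted p = 4.62e-13), and Dazl, an RNA-binding protein gene of germ cells, from 40.8 ± 2.87 to 96.6 ± 2.97 CPM. Smc1b, which encodes a cohesin subunit of meiosis, fell from 57.6 ± 6.71 to 15.9 ± 1.13 CPM, and Tuba3a from 154 ± 6.16 to 68.5 ± 1.38 CPM. The list's camera adjusted p was 0.000992, and adjusted p = 0.0939 with an estimated correlation.

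Imprinted genes, which are expressed from 1 parental copy, also rose on balance, though many did not pass. Of 22 tested, 13 rose, none fell and 9 did not pass, or 13 rose and 1 fell adjusted over the list alone. Ndn rose from 2.94 ± 0.0399 to 13.5 ± 0.921 CPM (SD, n = 3; log2 fold change 2.20 ± 0.15), Meg3 from 712 ± 32.0 to 1089 ± 32.8 CPM, Cdkn1c, a cell cycle inhibitor gene, by 1.32 ± 0.11 and Mest by 1.29 ± 0.11 on the log2 scale. Camera's adjusted p was 0.000783, and adjusted p = 0.17 with an estimated correlation. Of 11 Hox genes, 8 rose, none fell and 3 did not pass (camera adjusted p = 0.00781, and adjusted p = 0.218 with an estimated correlation). Most of their levels were low, with Hoxd8 at 1.67 ± 0.256 and 4.15 ± 0.547 CPM and Hoxd9 at 1.02 ± 0.345 and 2.55 ± 0.391 CPM. The highest were Hoxc13, at 26.0 ± 0.221 and 30.2 ± 0.790 CPM, and Hoxc12, at 12.96 ± 0.180 and 18.65 ± 1.84 CPM. These 2 genes rose less, by 0.21 ± 0.08 and 0.53 ± 0.105 on the log2 scale. Only 2 clustered protocadherin genes were tested, too few for camera. Pcdha11 rose from 0.653 ± 0.283 to 1.86 ± 0.0901 CPM, with 98.1% of its sequence shared with other genes, and the other did not pass.

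Most DNA replication genes fell. Of 35 tested, 29 fell, none rose and 6 did not pass, or 31 fell adjusted over the list alone. Cdc6, which loads the replicative helicase, fell from 62.5 ± 2.61 to 35.9 ± 1.12 CPM (SD, n = 3; log2 fold change −0.80 ± 0.06, adjusted p = 3.26e-09). The helicase subunit genes Mcm3, Mcm5 and Mcm7 fell by 0.55 ± 0.04, 0.55 ± 0.05 and 0.53 ± 0.04 on the log2 scale. The list's median log2 fold change was −0.38, with a camera adjusted p of 2.36e-09 that also passed with an estimated correlation (adjusted p = 0.0217). Genes of double-strand break repair and RIF1 partners fell as well, 14 of 23, with 2 that rose and 7 that did not pass. Besides H2afx, Brca2 fell by 0.44 ± 0.06 and Mdc1, which binds phosphorylated H2AX, by 0.43 ± 0.06. Ppp1cc, a catalytic subunit of the phosphatase that RIF1 recruits, fell by 0.50 ± 0.06, but shares 54.4% of its sequence with other genes. The break repair and RIF1 partner list had a camera adjusted p of 0.00358, and adjusted p = 0.0939 with an estimated correlation.

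Of 27 heterochromatin and silencing genes, 11 fell, none rose and 16 did not pass. Dnmt1, the maintenance DNA methyltransferase gene, fell from 764 ± 23.3 to 545 ± 17.1 CPM (SD, n = 3), Chaf1b fell by 0.48 ± 0.05, Hdac1 by 0.38 ± 0.05 and Cbx1 by 0.38 ± 0.05 on the log2 scale. Hdac1 shares 58.7% of its sequence with other genes. Camera's adjusted p of 0.035 became adjusted p = 0.218 with an estimated correlation, and the call was also lost without Rif1-KO replicate 1 (adjusted p = 0.06). Of 76 cytosolic ribosomal protein genes, 36 fell, none rose and 40 did not pass, or 35 adjusted over the list alone. Rpl6 fell by 0.33 ± 0.05, Rpl11 by 0.36 ± 0.05, Rpl19 by 0.32 ± 0.05 and Rpl29 by 0.40 ± 0.06, and all 4 share 38.3% to 79.3% of their sequence with other genes. The camera adjusted p was 0.00206, and adjusted p = 0.423 with an estimated correlation. Only 4 of the 70 replication-dependent histone genes in the table were tested, all at low levels. Of these 4, Hist1h1c rose, Hist2h3c1 fell and 2 did not pass. The median of 0.21 and camera's direction (up, adjusted p = 0.786) had the opposite sign to the mean of −0.41.

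**Figure D3:**
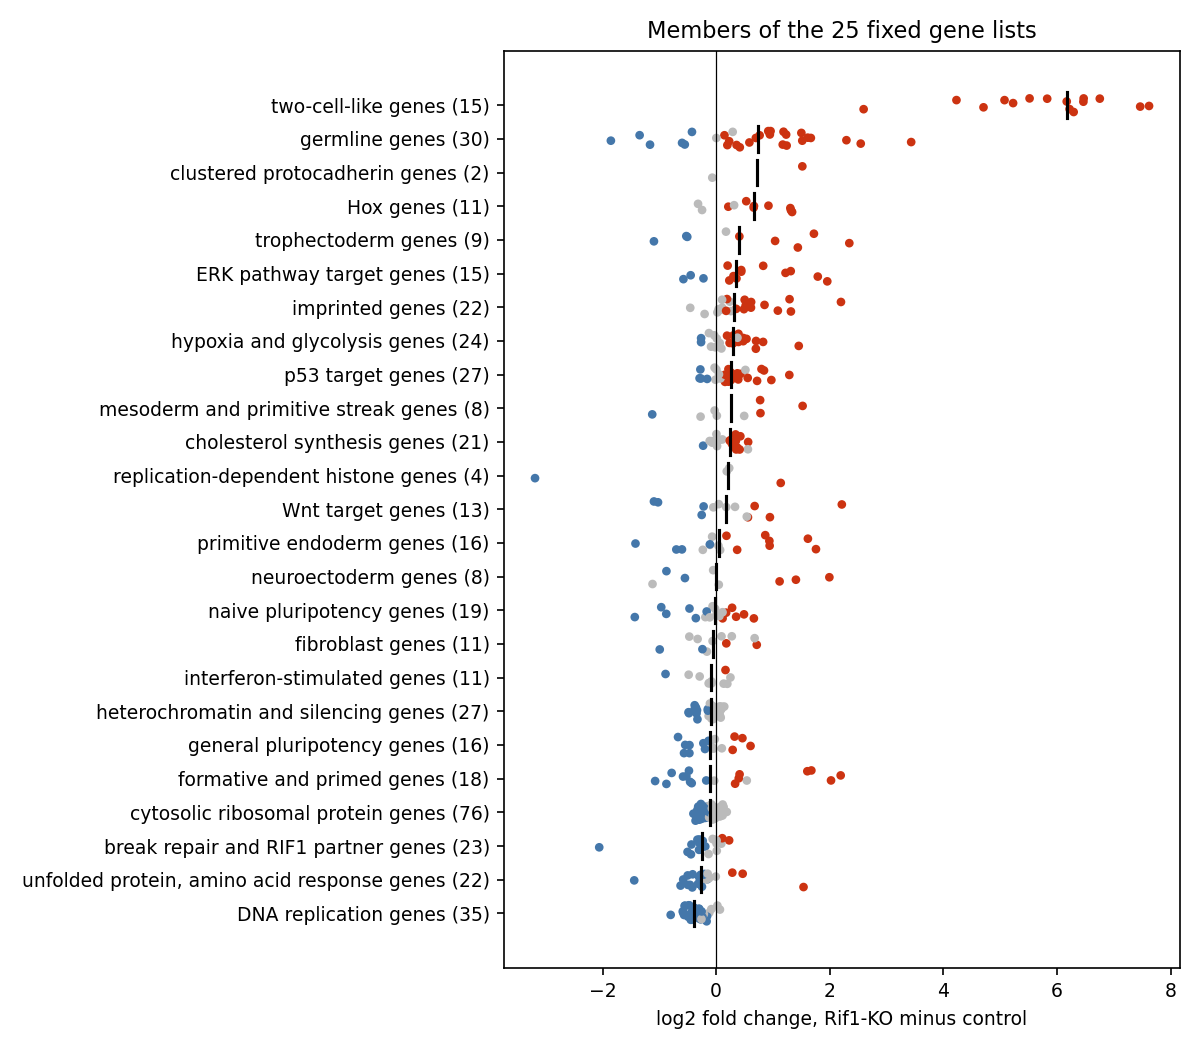
Log2 fold changes (Rif1-KO minus control, horizontal axis) of the tested members of the 25 fixed gene lists, 1 point per gene and 1 row per list with the number tested in brackets. Red points rose, blue points fell, grey points did not pass, and black bars mark medians, which run from −0.38 for DNA replication genes to 6.17 for two-cell-like genes; the medians of the primitive endoderm and neuroectoderm lists changed sign under another scaling.

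Target genes of p53 and of ERK rose on balance, with calls that did not hold with an estimated correlation. Of 27 p53 target genes 17 rose, 4 fell and 6 did not pass, or 18 and 4 adjusted over the list alone. Plk2 rose from 72.6 ± 3.40 to 142 ± 3.08 CPM (SD, n = 3), Btg2 from 120 ± 5.27 to 208 ± 1.97 CPM, Perp by 1.29 ± 0.12 and the apoptosis gene Pmaip1 by 0.84 ± 0.07 on the log2 scale. The 4 that fell were Sesn2, Bax, Gdf15 and Ei24, by 0.16 to 0.29 on the log2 scale. Cdkn1a and Mdm2 rose by only 0.16 ± 0.05 and 0.22 ± 0.04. Camera's adjusted p was 0.00416, and adjusted p = 0.261 with an estimated correlation. Of 15 ERK target genes 11 rose, 3 fell and 1 did not pass, or 12 and 3 adjusted over the list alone. Phlda1 rose by 1.96 ± 0.20, Dusp5, a phosphatase that acts on ERK, by 1.31 ± 0.18 and Fos by 1.22 ± 0.14, while Spred2 fell by 0.58 ± 0.06. The list's adjusted p was 0.00749, and adjusted p = 0.218 with an estimated correlation. Spry2 and Etv4 fell as well, and Dusp6 did not pass. The 2i medium inhibits this pathway, and the headers name 2i for the control libraries alone. Whether a difference in medium bears on this list was not tested.

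Metabolic lists moved in different directions. Of 24 hypoxia and glycolysis genes 14 rose, 2 fell and 8 did not pass (camera adjusted p = 0.00392, and adjusted p = 0.0939 with an estimated correlation). The glucose transporter genes Slc2a3 and Slc2a1 rose from 2017 ± 166 to 3284 ± 170.4 CPM and from 300.0 ± 10.7 to 434 ± 8.94 CPM (SD, n = 3), P4ha2 rose by 1.45 ± 0.08 and Ndrg1 by 0.83 ± 0.06. Of 21 cholesterol synthesis genes 11 rose, 1 fell and 9 did not pass, with Cyp51 at 0.43 ± 0.05, Stard4 at 0.41 ± 0.05 and Sc4mol at 0.35 ± 0.04 on the log2 scale (camera adjusted p = 0.0152, and adjusted p = 0.261 with an estimated correlation). Of 22 unfolded protein and amino acid response genes 15 fell, 3 rose and 4 did not pass. Shmt2 and Psat1, enzymes of serine metabolism, fell by 0.63 ± 0.05 and 0.58 ± 0.04 and the amino acid transporter gene Slc7a5 by 0.50 ± 0.05, while the stress transcription factor gene Atf3 rose by 1.54 ± 0.12. Camera's adjusted p was 0.00124, and adjusted p = 0.0939 with an estimated correlation.

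Camera set neither interferon-stimulated nor Wnt target genes apart from the remaining genes. Of 11 interferon-stimulated genes, Stat2 rose, Dhx58 fell and 9 did not pass (camera adjusted p = 0.384, and adjusted p = 0.000781 by fry, with direction down). Both calls were lost with DESeq2 (adjusted p = 0.0837 and 0.0918), and that of Stat2 also without control replicate 3 (0.126), without Rif1-KO replicate 2 (0.0634) and with the offset (0.0807). Of 13 Wnt target genes, 4 rose, 4 fell and 5 did not pass (camera adjusted p = 0.764). Ccnd1, the cyclin D1 gene, fell from 68.7 ± 2.07 to 33.8 ± 0.921 CPM (SD, n = 3) and Ascl2 by 1.09 ± 0.23 on the log2 scale, while Cdx1 rose by 2.21 ± 0.39 and Nkd2 by 0.95 ± 0.17. Except where given, adjusting over the list alone left the counts of each list as stated. In all, camera called 13 of the 24 lists it tested, and with an estimated correlation 2, the two-cell-like and DNA replication lists. The filter on low counts fixed the direction of the tested two-cell-like genes. With every gene read at least once kept, camera with an estimated correlation called the same 2 lists (adjusted p = 0.0181 and 0.0288). There, two-cell-like members without a control count could still only rise.

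No single chromosome passed, and X lay farthest from the remaining genes. Of 500 tested X-linked genes 187 rose and 77 fell, and their median log2 fold change lay 0.15 above that of the remaining genes. The difference was 0.10 for chromosome 3 and −0.08 for chromosome 19. By exact two-sided permutation of the libraries the p was 0.1, the smallest that 3 against 3 allows, for X and for 17 other chromosomes, and 0.111 after Benjamini-Hochberg adjustment over 20 chromosomes, so this test does not set X apart. With the offset for GC content and length, the X difference was 0.10. Fold changes of adjacent genes correlated at a Spearman's rho of 0.209 across 13743 gene pairs, against at most 0.0489 in 10000 shuffles of gene order (p = 1e-04, the smallest they can give). The shuffles do not test the groups. Neighbours also varied together in all 9 other splits of the libraries into 3 and 3, which keep part of the difference between the groups, with rho from 0.085 to 0.16. With pairs within 100 kb left out rho was 0.127, against at most 0.0975 in shuffles and 0.0495 to 0.112 in the other splits.

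More genes were detected in the libraries labelled Rif1-KO. Genes with at least 10 counts numbered 13889 ± 138 in control and 14493 ± 200 in the libraries labelled Rif1-KO (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). With all libraries thinned to the smallest total the numbers were 13777 ± 43.2 and 14137 ± 12.8. Mitochondrial genes took 3.27% ± 0.513 and 2.77% ± 0.334 of counts (exact p = 0.2), and cytosolic ribosomal protein genes 4.74% ± 0.0428 and 4.38% ± 0.166 (exact p = 0.1). The 20 most counted genes took 8.20% ± 0.518 and 7.85% ± 0.343 (exact p = 0.5). Replication-dependent histone genes took 0.00180% ± 0.000115 and 0.00233% ± 0.000255 (exact p = 0.1). So small a share, in libraries made with an mRNA kit, does not measure histone expression.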

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

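The offset for GC content and length, the thinning, the 2-fold minimum and the estimated correlation without a filter were chosen after seeing the data. Besides Rif1, 115 named genes were followed, with 0 changes of direction under the alternatives that gave them a value. Of those values 15 lost the call, all of Dhx58, Stat2, Mesp2, Kdr or Twist1. These genes were chosen for large changes or a small adjusted p in the main fit on the same libraries. That their direction held does not measure how the 7251 calls would hold. Rif1 was lower under all 18 alternatives. It passed the threshold with DESeq2 size factors (−0.12), upper-quartile factors (−0.12), no filter on low counts (−0.12), a filter of 1 CPM in 3 libraries (−0.12), DESeq2 (−0.13), limma-voom (−0.12), robust dispersion (−0.12) and the offset (−0.35). Without each library in turn it ran from −0.17 to −0.094. The cause was not tested. The count of 7251 genes called ran from 6368 to 7099 without each library in turn and was 5568 with DESeq2. It was 2192 with a 1.5-fold minimum, 934 with a 2-fold minimum and 3248 when tested against a 1.2-fold change, as fewer genes change that much. Called lists numbered 13 with camera, 2 with an estimated correlation, with and without the filter on low counts, and 19 with fry, which does not compare lists with other genes. Fry added the naive, general, formative, interferon-stimulated, primitive endoderm and trophectoderm lists, and gave the opposite direction to camera for the naive (adjusted p = 0.0491) and formative (adjusted p = 0.0174) lists, and the cause was not tested. The X chromosome's difference ran from 0.13 to 0.16 without each library in turn and was 0.10 with the offset. At 8383632 to 10980777 counts per library, changes of 1.2-fold were recovered for 34% of simulated genes. Far fewer genes changed in that simulation than were called here, so this share need not hold for the real test.

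Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at 0.0793, −0.0646 and 0.0461. With the number as a block, 7386 genes were called, 7190 of them shared with the fit without it, Rif1 passed (−0.12), the heterochromatin list did not (adjusted p = 0.0569), and not every library correlated best with its own number.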

Other observations

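The YAP and TAZ target list and the test for fibroblasts were chosen after results had been seen, as were the offset for GC content and length and the ratio over two-cell-like members with little shared sequence. Among well expressed genes the steepest rises included those of Cyr61 and Ctgf, textbook targets of the YAP and TAZ coactivators, which respond to cell shape, adhesion and Hippo signalling. Cyr61 rose from 9.53 ± 0.306 to 169 ± 3.43 CPM (SD, n = 3; log2 fold change 4.14 ± 0.07, adjusted p = 1.05e-19 by edgeR) and Ctgf from 9.92 ± 0.664 to 132 ± 1.04 CPM (3.73 ± 0.07). Jub, Amotl2, Myof and Lats2 rose by 1.38 ± 0.05, 0.99 ± 0.05, 0.86 ± 0.05 and 2.20 ± 0.22 on the log2 scale. Lats2 shares 56.5% of its sequence with other genes. Of 17 tested genes on a YAP and TAZ target list, 12 rose, 1 fell (Dock5) and 4 did not pass. The list's median log2 fold change was 0.63, with an unadjusted camera p of 5.35e-05, and an unadjusted p of 0.0121 with an estimated correlation. Actb, the cytoskeletal actin gene, went from 1261 ± 19.6 to 1867 ± 10.5 CPM.

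The rise of YAP and TAZ targets was set against 3 technical explanations. With Cyr61, Ctgf and Jub, the genes that prompted the list, left out, 9 of the remaining 14 rose. Camera in limma then gave an unadjusted p of 0.00653, which argues against a list resting on those genes alone, although the median dropped from 0.63 to 0.40 and the p with an estimated correlation was 0.0445 (unadjusted). With the offset for GC content and length the p was 1.09e-05 and the median 0.54, which argues against that trend as the whole cause. Fibroblasts or feeder cells would bring collagen, and the summed gain of Col1a1, Col1a2 and Col3a1 (2.93 ± 1.47 to 3.10 ± 0.450 CPM) was 0.107% of the gain of Cyr61. The pattern was found and tested on the same data, and loss of Rif1, 4-OHT or another medium in one group, cell density and adhesion were not tested and stay open.

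The rise of two-cell-like genes was likewise weighed. The test planned for reads shared between copies, the median log2 fold change of tested members with under 10% shared sequence (4.36, with Spz1 at its bound), decides nothing, because the filter on low counts kept these members only for their counts in the libraries labelled Rif1-KO. Over all 4 members in the table with under 10% shared sequence, tested or not (Spz1, Zfp352, Lmx1a and Rfpl4), counts were 9 in control and 185 in the libraries labelled Rif1-KO, a ratio of 18.1 (95% interval 9.33 to 40.2). This argues against shared reads as the whole cause, while the level of single copies among the other members stays uncertain. Tmem92-ps (2.01% shared), whose current name Tmem92 is on the list, was not counted among the 4. A background of genomic DNA does not account for the rise. The gain per gene was read from 1574 odorant and vomeronasal receptor genes, which are silent in such cells. It was at most 0.183% (upper 95% counting bound) of the median gain of the list's tested members. The filter kept those members for their counts in the libraries labelled Rif1-KO. Over all 29 members in the table the sum went from 1.62 to 76.1 CPM, against 21.9 to 30.2 CPM over the receptor genes. Silent genes give no unspliced RNA, so a background of that kind was not tested. Exposure to 4-OHT in one group cannot be told apart from the loss of Rif1, because 0 control libraries carry TAM in their header and all 3 labelled Rif1-KO do. A difference in medium is confounded in the same way, since 2i stands in the headers of the control libraries alone. Loss of Rif1, the difference the labels name, was not tested as a cause and stays open.

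Large changes were mostly increases, with 748 genes at least 2-fold higher against 186 lower, a ratio of 4.02. Thinning every library to the smallest total gave 4.13, and the offset for GC content and length gave 3.42, so neither depth nor that trend accounts for the asymmetry. The receptor genes' gain per gene was at most 0.213% of the median gain of the genes at least 2-fold higher (3.55 CPM). The genes at least 2-fold higher were chosen for their rise, so their median gain is large by selection. The percentage therefore cannot decide whether a background of genomic DNA adds to the asymmetry. It shows only that a gain of the receptor genes' size falls far short of that median. A background of unspliced RNA was not tested, since silent genes give none. Summed over those receptor genes the level was 21.9 ± 1.32 CPM in control and 30.2 ± 1.83 CPM in the libraries labelled Rif1-KO (SD, n = 3; exact permutation p = 0.1, the smallest possible). Of the 748 genes, 496 had a control mean of at least 1 CPM. Loss of Rif1 and 4-OHT or another medium in one group were not tested as causes and stay open.

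Across the 20 chromosomes, the median difference of each followed the mean GC content of its transcripts, with Pearson's r of −0.911 and Spearman's rho of −0.894 (permutation p = 1e-05 for each, the smallest given), and r of −0.94 without the 2 chromosomes farthest from the median GC content. Chromosomes are not independent samples, and this relation was looked for after the chromosome values had been seen. Across 13894 genes, fold change correlated with GC content at a Spearman's rho of −0.154 and with transcript length at 0.131. The correlation of adjacent genes was 0.198 over pairs of different symbol families, above the shuffles (at most 0.0509), which argues against gene families as its whole cause, and 0.171 with the offset. Other splits of the libraries, which keep part of the difference between the groups, gave 0.0745 to 0.155 over the same pairs.

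The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these 10 splits, 1, the real one, gave as many as 7251 genes, and the highest of the other splits gave 0 with edgeR, and 0 with DESeq2 and limma-voom. At an unadjusted p under 0.05, edgeR called 8058 genes in the real split and 67 to 525 in the others. Each other split puts both labels on both sides, so the difference between the groups adds to the spread within a side. Few calls there were fixed beforehand, and these splits give no baseline for the 7251. For lists called, 1 split, the real one, reached 13, and the highest other gave 10. For adjacent genes, 1 split, the real one, reached 0.209, and the highest other gave 0.16.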
